A study of Homo sapiens with 6 samples.

How the data were processed

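RNA was measured in 6 libraries of Huh7 cells, 3 from wild-type cells and 3 from cells in which UBE2S had been knocked out. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol, mRNA was enriched on oligo(dT) beads and fragmented, and libraries were made with a NEBNext Ultra kit and sequenced on an Illumina NovaSeq instrument. Per the submitters' processing notes, Bowtie2 2.2.8, HISAT2, StringTie 1.3.1 and DESeq2 were used, with no role given for each. The program that made the gene values, its annotation, its genome build and the way the knockout was made are not given in the sources used here. Whether the library kit or the counting kept the strand is not given either, so reads of a gene and of an antisense partner cannot be told apart.

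The authors deposited 1 table of estimated counts per gene for the 6 libraries. The values were not normalized: they summed to between 21840499 and 27910396 per library. In each library 2670 to 2835 genes had an estimate that was not a whole number, as programs that share reads between similar genes give. Such sharing makes the values of near-identical genes, such as metallothioneins, histones and HLA genes, less certain than those of other genes. The estimated counts were rounded to whole numbers before any test. The table held 20289 genes, of which 20171 (99.4%) were matched by identifier to GENCODE release 29, which gave the GRCh38 positions; 98.1% of the matched genes were protein coding.

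Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, which left 13265, and libraries were scaled by TMM. Quasi-likelihood F tests compared knockout with wild type, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors were derived from the fitted log2 fold change and its F statistic. CPM (counts scaled to the same total in each library) were computed on the TMM-scaled library size and are given as mean ± SD over 3 libraries. Where a group had few counts, the fold was also given as a ratio of summed counts with an exact 95% binomial interval, which covers counting error alone; where it had 0 counts, a lower bound was set from 3 counts over the group.

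Before the data were examined, 40 gene lists were fixed from textbook knowledge, and 38 with at least 5 tested members were compared with all other tested genes by camera in limma 3.58.1, two-sided, with a preset correlation between genes of 0.01. List p-values were adjusted over the 38 lists. The rule for the genes named was fixed at the same time. It took UBE2S, the 12 genes with the largest higher and the 12 with the largest lower log2 fold change among called genes with a mean of at least 5 CPM, groups that did not overlap and a gene symbol. It added the 5 called genes with the smallest p in each direction, and in each list up to 3 called members per direction with the largest change, or the 2 most abundant where none was called. Genes named outside this rule are said to have been chosen after their values were seen. In addition, 5 lists were written after the values were seen and are described by counts and medians alone.

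Positions were examined after the fold changes had been seen. Each of 286 regions of 10 Mb with at least 10 tested genes was compared with 10000 random gene sets of its size by the median log2 fold change. For each gene, the median of the 25 tested genes on each side gave the shift of its neighbourhood.

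The gene and list tests were tested on simulated data drawn from the means and library sizes of these libraries, with 200 of the 13265 genes changed. For UBE2S knockout against wild type, the edgeR test recovered 58% of 50 genes with a log2 change of 0.3, 76% at 0.5, 90% at 1 and 100% at 2. It also called 14 unchanged genes, 7.95% of its calls, against 8 for DESeq2 1.42.0. Camera found 20 of 20 lists of 20 members, each member shifted by 0.3, with the preset and with an estimated correlation. These genes were simulated independently of each other, and nearly all others were unchanged, whereas 60.1% were called in the data. How often edgeR and camera find changes in such data, where list members also scatter, was not measured. The region test was tried on the observed log2 fold changes, shuffled over the genes. It found 20 of 20 regions of at least 30 genes shifted by 0.3 and 0 of 266 others, and smaller regions or shifts were not tried.

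The alternatives tried were other library scalings, other filters on low counts, DESeq2 (with its own filter in place of filterByExpr, and its statistics for all genes with a p-value tested by the preranked form of camera), limma-voom, the replicate number as a block, each library left out in turn, a minimum fold, a stricter threshold, a correlation between genes estimated from the data, fry, and lists restricted to members of at least 10 CPM. Removing the neighbourhood shift and removing a trend in GC content and transcript length were added after the data had been seen.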

Results

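The series measured poly(A) RNA of Huh7 cells, a human hepatocellular carcinoma line, to find genes that act downstream of UBE2S. UBE2S is a ubiquitin-conjugating enzyme that works with the anaphase-promoting complex, the ubiquitin ligase that drives exit from mitosis. There were 3 wild-type and 3 UBE2S knockout libraries. Their totals were 27594276, 23300336 and 27910396 estimated counts in wild type and 21840499, 23337278 and 25840104 in the knockout, and 15442 to 15694 genes were detected in each. Mitochondrially encoded genes took 5.03% to 6.47% of the counts in wild-type libraries and 6.04% to 6.23% in knockout libraries. The libraries separated by group: principal component 1 of the 500 most variable genes held 83.8% of their variance, and Pearson correlations across genes were 0.994 to 0.995 within groups and 0.967 to 0.969 between them. No library was a copy of another, since each pair within a group differed beyond sampling noise. Wild-type replicate 1 stood somewhat apart, with a chi-square per degree of freedom of 8.41 and 10.9 against the other wild-type libraries, which gave 1.80 between themselves. The labels do not say whether the replicates were separate cultures or clones, so the p-values measure only the spread between these samples, which may be technical.

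In the knockout, UBE2S mRNA fell by 2.29 on the log2 scale (SE 0.04, edgeR adjusted p = 1.6e-12). Its level was 224 ± 9.37 CPM in wild type and 45.7 ± 1.70 CPM in the knockout (mean ± SD, n = 3 each). The libraries held 6332, 5129 and 6068 counts in wild type and 1046, 1062 and 1147 counts in the knockout, so every knockout library lay below every wild-type library. The gene (ENSG00000108106) lies on the minus strand of chromosome 19, from 55399745 to 55407777 in GRCh38. GENCODE release 29 gives it 3 protein-coding transcripts, of 4, 5 and 4 exons. The edited position is not given in the sources used here, and an mRNA level does not show whether protein was made from the transcripts that remained.

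**Figure D1:**
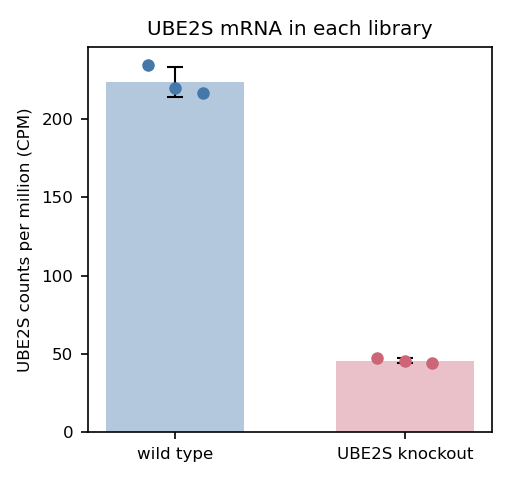
UBE2S mRNA in CPM in wild-type and UBE2S knockout libraries; points are the 3 libraries of each group, bars their mean and error bars their SD. The wild-type mean is 224 CPM and the knockout mean 45.7 CPM.

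The knockout libraries differed from wild type at many genes, and the largest differences were losses of expression. COL1A2, a chain of type I collagen, fell from 139 ± 8.94 to 0.338 ± 0.0768 CPM, with 10893 wild-type counts against 24 in the knockout, a ratio of 413 (95% interval 277 to 645). SDR42E1, a member of the short-chain dehydrogenase family, fell from 1766 counts to 3, a ratio of 536 (183 to 2599), and the metallothionein gene MT1G from 1544 to 6, a ratio of 234 (107 to 639). WNT5A, which encodes a secreted Wnt ligand, fell from 1053 counts to 4, a ratio of 239 (93.3 to 881). In the other direction, the Notch receptor gene NOTCH3 rose from 2.04 ± 0.689 to 43.9 ± 1.79 CPM, a log2 fold change of 4.44 (SE 0.12, edgeR adjusted p = 3.3e-11).

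Further large falls were those of the receptor phosphatase gene PTPRG (log2 fold change -6.56, SE 0.15), the adhesion molecule gene L1CAM (-6.13, SE 0.16), the non-muscle myosin gene MYH14 (-5.75, SE 0.25), the protocadherin-related gene CDHR5 (-5.48, SE 0.15) and the sortilin-family receptor gene SORCS2 (-5.23, SE 0.14). MICB, a stress-induced ligand of an activating receptor on natural killer cells, fell from 13.5 ± 0.791 to 0.404 ± 0.0779 CPM. DCAF4L2 (-6.40, SE 0.13) and NAV3 (-4.98, SE 0.17) completed the 12 largest falls among genes with a mean of at least 5 CPM. Abundant genes with some of the smallest p-values were AKR1B1, the aldose reductase gene, which fell from 95.9 to 9.84 CPM, GATM, an enzyme of creatine synthesis, from 72.9 to 9.93 CPM, and the complement gene C3, from 3481 to 1258 CPM. Their log2 fold changes were -3.28 (SE 0.05), -2.88 (SE 0.05) and -1.47 (SE 0.03), with edgeR adjusted p of 3.1e-13, 1.6e-12 and 2.9e-12.

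Among genes with a mean of at least 5 CPM, the largest increases after NOTCH3 were smaller than the largest falls. PRSS35 rose by 3.59 (SE 0.18) on the log2 scale, AEBP1 by 2.95 (SE 0.13) and IGFBP2, which binds insulin-like growth factors, by 2.89 (SE 0.10). SPP1, the gene for the secreted matrix protein osteopontin, rose from 2.91 ± 0.327 to 17.9 ± 0.693 CPM. OLFM2 (2.31, SE 0.10), the glutamate transporter gene SLC1A3 (2.19, SE 0.07), the adenylate cyclase gene ADCY5 (2.14, SE 0.10), the Wnt receptor gene FZD2 (2.13, SE 0.09), PCSK1N (2.03, SE 0.07), FLNC and the sucrase-isomaltase gene SI (1.95, SE 0.09) followed. FLNC, which encodes an actin-binding filamin, rose from 26.6 to 106 CPM and had the smallest p among increases (edgeR adjusted p = 3.1e-12). Also among the 5 smallest were UACA (1.31, SE 0.03), the Wnt receptor gene FZD5 (1.26, SE 0.03), the collagen gene COL12A1 (1.59, SE 0.04) and the chondroitin sulfotransferase gene CHST3 (1.09, SE 0.03).

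**Figure D2:**
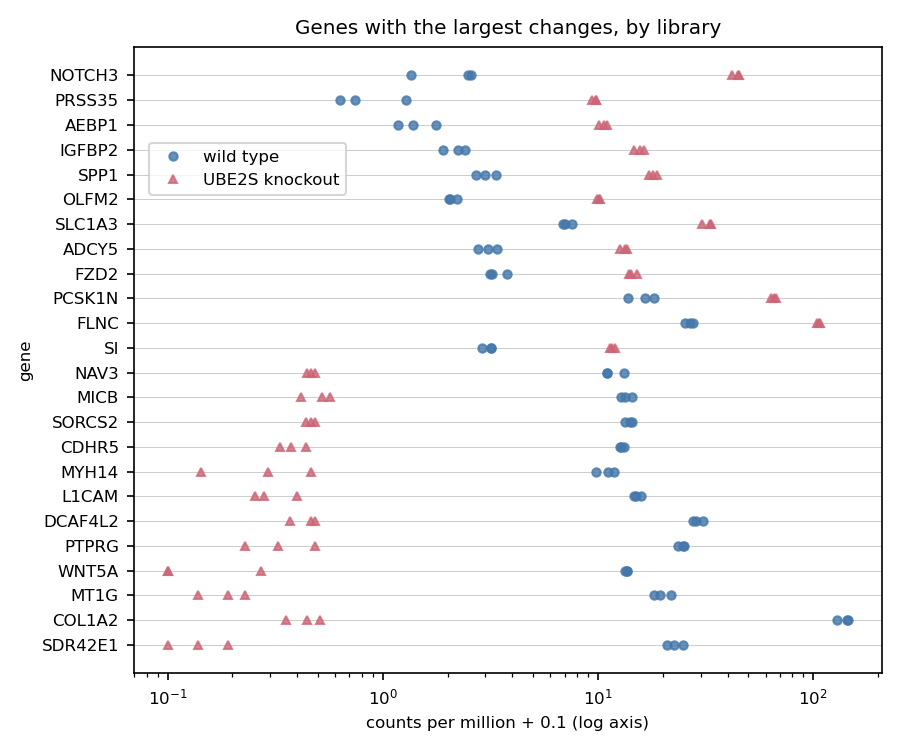
CPM plus 0.1, on a log axis, of the 12 genes with the largest increases and the 12 with the largest falls among those with a mean of at least 5 CPM, with 1 point per library (circles, wild type; triangles, UBE2S knockout). NOTCH3 rises from 2.04 to 43.9 CPM and COL1A2 falls from 139 to 0.338 CPM, and no gene shown has overlapping groups.

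In all, 7975 of 13265 tested genes (60.1%) had an edgeR adjusted p below 0.05, 3903 higher and 4072 lower in the knockout. Most were small: 5462 had an absolute log2 fold change below 0.5, while 814 reached 1 (387 higher, 427 lower) and 197 reached 2 (59 higher, 138 lower). The 3 knockout values lay wholly above or below the 3 wild-type values at 8733 genes (65.8%), where chance gives 10%. Small changes in many genes lay beside neighbours that moved the same way, as described for the chromosomes further on. Calls were common outside the shifted regions too. Of 4545 genes in shifted regions 71.3% were called, against 54.4% of 8562 genes in other regions.

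Of the 40 gene lists, 9 passed the camera test, 7 lower and 2 higher in the knockout. With a correlation between genes estimated from the data, 0 of the 38 tested lists passed and 5 had an unadjusted camera p below 0.05; the adjusted p-values are given with each list. Cholesterol biosynthesis and uptake had the smallest p: 21 of 23 genes fell and 1 rose, with a median log2 fold change of -0.28 (camera adjusted p = 7.4e-05; adjusted p = 0.19 with an estimated correlation). Examples were the sterol synthesis enzymes CYP51A1 (-0.65, SE 0.03) and NSDHL (-0.60, SE 0.05), against PMVK (0.53, SE 0.08). Replication-dependent histones, whose mRNAs lack a poly(A) tail, had 11 of 14 genes lower and 0 higher, with a median of -0.61 (camera adjusted p = 6.1e-04; adjusted p = 0.19 with an estimated correlation). H2BC9 (-1.47, SE 0.12), H4C8 (-0.83, SE 0.08) and H3C10 (-0.76, SE 0.11) fell most. Metallothioneins and zinc transport had 7 of 8 genes lower and 0 higher (median -0.47, camera adjusted p = 0.0044; adjusted p = 0.21 with an estimated correlation), with MT1X (-0.82, SE 0.09) and MT1F (-0.60, SE 0.04) beside the near loss of MT1G.

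Endoplasmic reticulum chaperones and the unfolded protein response had 16 of 21 genes lower and 1 higher (median -0.22, camera adjusted p = 0.0044; adjusted p = 0.21 with an estimated correlation). CRELD2 (-1.05, SE 0.05), SDF2L1 (-0.61, SE 0.11) and the stress sensor ERN1 (-0.47, SE 0.05) fell, and SEL1L rose (0.15, SE 0.03). Targets of YAP and TAZ, the coactivators restrained by the Hippo pathway, rose at 10 of 13 genes and fell at 1 (median 0.53, camera adjusted p = 0.0011; adjusted p = 0.19 with an estimated correlation). ANKRD1 rose from 107 to 259 CPM, CCN2 from 218 to 440 CPM and AMOTL2 from 151 to 289 CPM, while NT5E fell (-1.10, SE 0.05). Among targets of the stress-induced transcription factor ATF4, 12 of 19 rose and 4 fell (median 0.23, camera adjusted p = 0.043; adjusted p = 0.45 with an estimated correlation). The amino acid transporter genes SLC7A11 (1.07, SE 0.04) and SLC7A5 (0.79, SE 0.04) and the lipoprotein receptor gene VLDLR (0.80, SE 0.06) rose. NUPR1 (-1.24, SE 0.18), CHAC1 (-0.97, SE 0.08) and CEBPG (-0.31, SE 0.04) fell. CEBPG (0.081) changed sign and lost its call once a shift shared with chromosome neighbours, described further on, was removed.

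Complement and coagulation factors had 15 of 23 genes lower and 6 higher (median -0.34, camera adjusted p = 0.043; adjusted p = 0.45 with an estimated correlation). C3, the kininogen gene KNG1 (-1.07, SE 0.05) and CFI (-0.91, SE 0.04) fell, whereas C6 (1.19, SE 0.17), MBL2 (1.00, SE 0.07) and the prothrombin gene F2 (0.40, SE 0.03) rose. DNA replication and S phase had 15 of 32 genes lower and 5 higher (median -0.10, camera adjusted p = 0.043; adjusted p = 0.45 with an estimated correlation). The thymidylate synthase gene TYMS (-0.69, SE 0.03) fell, as did CHAF1A and UHRF1 (both -0.49), and MCM6 rose (0.23, SE 0.03). Once a shift shared with chromosome neighbours, described further on, was removed, the median of this list was -0.057 (camera adjusted p = 0.23), and CHAF1A (0.035) and UHRF1 (0.025) had changed sign and lost their call. Cytosolic ribosomal proteins had 15 of 30 genes lower and 3 higher (median -0.08, camera adjusted p = 0.043; adjusted p = 0.52 with an estimated correlation). RPL14 (-0.55, SE 0.04), RPL11 (-0.49, SE 0.04) and RPS16 (-0.47, SE 0.03) fell and RPLP1 (0.36, SE 0.11) rose. Of these, RPS16 (-0.064) and RPLP1 (0.084) lost their call with the shift of neighbours removed. RPLP1 was also not called with DESeq2 (adjusted p = 0.10). The tests of the last 3 lists and of the ATF4 targets were close to the threshold. Each of these 4 lists lost its call when certain single libraries were left out, with camera adjusted p-values then between 0.052 and 0.13.

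**Figure D3:**
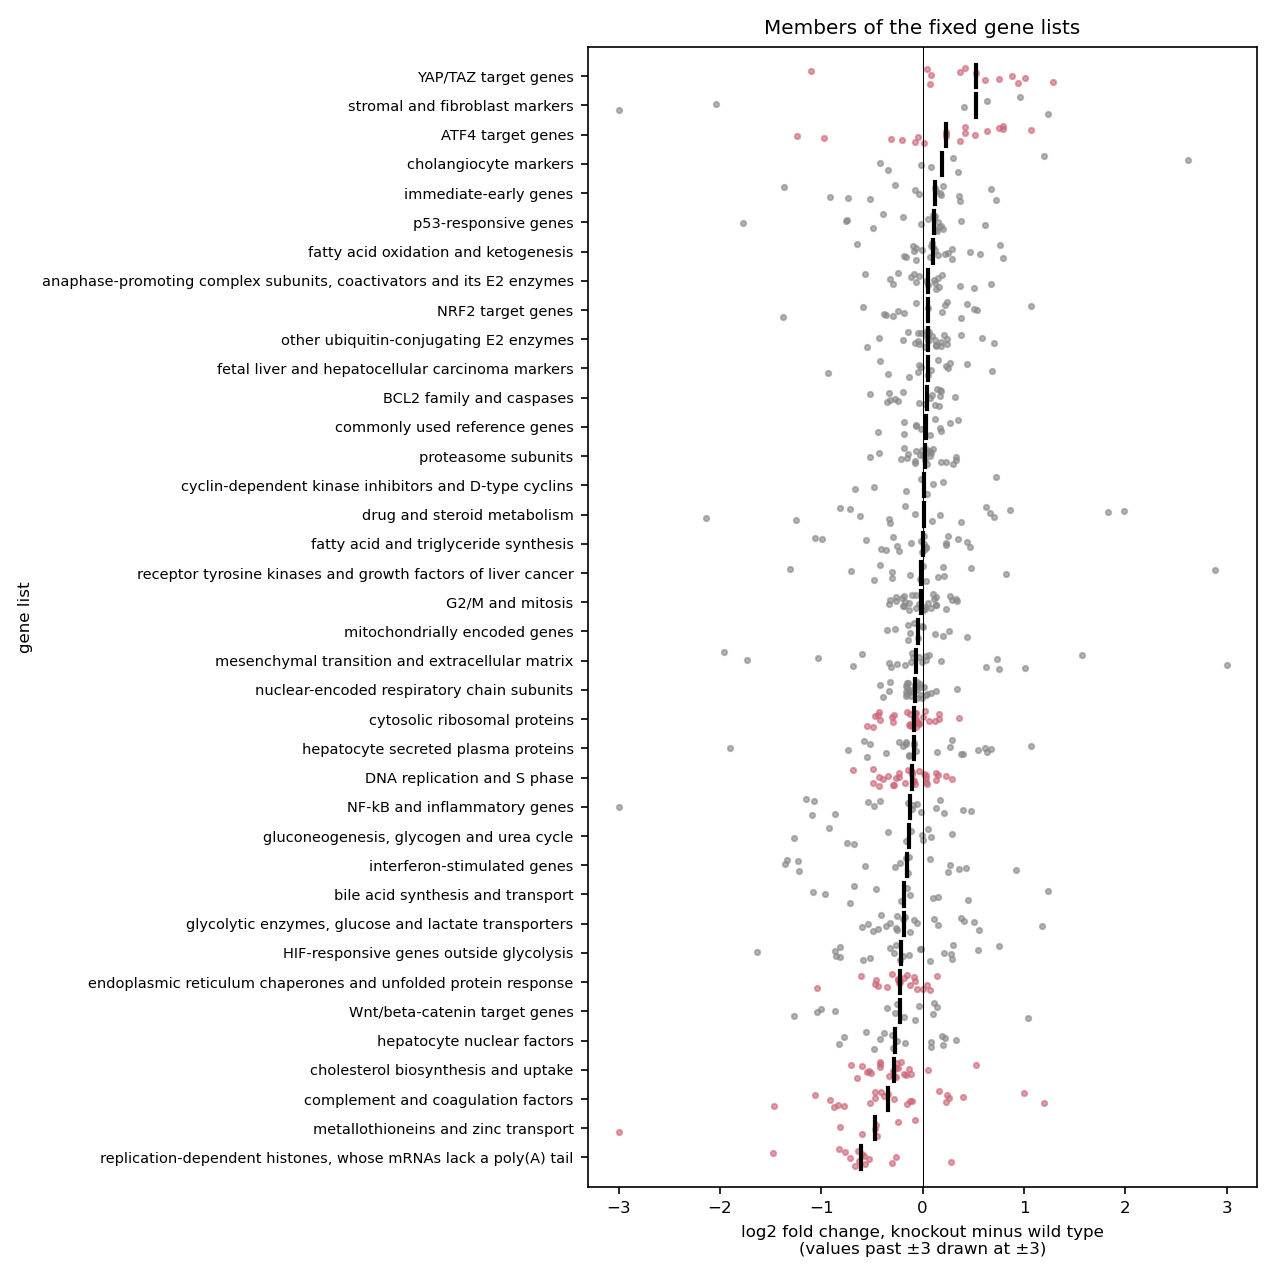
Log2 fold change, knockout minus wild type, of each tested member of the 38 tested gene lists (points), with the median of each list (black bars) and values past ±3 drawn at ±3. Lists that passed the camera test are in red; medians run from -0.61 for replication-dependent histones to 0.53 for YAP/TAZ targets.

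The other lists did not pass the camera test, although most held genes that changed. In the anaphase-promoting complex, with which UBE2S works, 8 of 19 genes were higher and 4 lower, with ANAPC16 (0.67, SE 0.04) and the coactivator genes FZR1 (-0.57, SE 0.06) and CDC20 (-0.32, SE 0.03) among them. With the shift of their chromosome neighbours removed, ANAPC16 was at 0.19, and FZR1 (-0.053) and CDC20 (-0.064) lost their call. Other ubiquitin-conjugating enzymes had 12 of 28 genes higher and 4 lower, including UBE2L6 (0.58, SE 0.06) and CDC34 (-0.55, SE 0.03). G2/M and mitosis genes went both ways, 8 of 30 higher and 12 lower, and the largest changes were those of KIF11 (0.34, SE 0.03) and CENPE (-0.33, SE 0.05). Of 8 cyclin-dependent kinase inhibitors and D-type cyclins, 2 were higher and 2 lower: CDKN2D (0.73, SE 0.13), CDKN2B (0.20, SE 0.04), CDKN1A (-0.67, SE 0.10) and CDKN1B (-0.48, SE 0.04). Genes responsive to p53 had 4 of 19 higher and 6 lower, with PLK3 (-1.77, SE 0.14) and GDF15 (0.61, SE 0.05). The BCL2 family and caspases had 4 of 18 higher and 6 lower, with CASP8 (-0.52, SE 0.05) and MCL1 (0.18, SE 0.03). Proteasome subunits had 7 of 25 higher and 8 lower, with PSMB4 (0.33, SE 0.03) and PSMB5 (-0.51, SE 0.04). With the shift of neighbours removed, KIF11 (0.064), CDKN1B (-0.071) and PSMB4 (0.040) lost their call, MCL1 (-0.075) changed sign and lost it, and CDC34 was at -0.10.

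Metabolic lists were also mixed. Glycolytic enzymes and glucose and lactate transporters had 12 of 22 genes lower and 5 higher, with HK2 (-0.60, SE 0.04), PFKFB3 (-0.54, SE 0.04) and PFKM (0.51, SE 0.05). The list missed the threshold with edgeR (median -0.19, camera adjusted p = 0.23) but not with DESeq2 (adjusted p = 0.024). With the shift of chromosome neighbours removed from the edgeR values, the glycolysis median was -0.046 (camera adjusted p = 0.83). HIF-responsive genes outside glycolysis had 11 of 22 lower and 6 higher (camera adjusted p = 0.24). Among them the collagen cross-linking oxidase genes LOX, from 105 to 33.9 CPM, and LOXL2 (-0.87, SE 0.06) fell, and STC2 (0.75, SE 0.04) rose. Fatty acid oxidation and ketogenesis had 10 of 22 higher and 2 lower, led by CPT1A (0.57, SE 0.04) among abundant members. Fatty acid and triglyceride synthesis had 6 of 22 higher and 9 lower; the lipid droplet gene PLIN2 fell from 197 to 94.4 CPM. Nuclear-encoded respiratory chain subunits had 1 of 30 higher and 11 lower (SDHB -0.42, SE 0.05), and gluconeogenesis, glycogen and urea cycle had 0 of 12 higher and 7 lower (CPS1 -1.27, SE 0.08). Without wild-type replicate 1, the respiratory chain list passed the camera test (adjusted p = 0.006), against a camera adjusted p of 0.14 with all libraries. With all libraries and an estimated correlation the camera adjusted p was 0.78. Of 13 mitochondrially encoded genes, 2 were higher and 2 lower, with MT-CO1 at 0.44 (SE 0.07) and MT-ND2 at -0.36 (SE 0.08). NRF2 targets had 8 of 17 higher and 7 lower, with NQO1 (0.51, SE 0.04) and PGD (-0.59, SE 0.04).

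Among liver genes, plasma proteins had 9 of 25 higher and 12 lower: haptoglobin (HP) fell from 29.9 to 8.05 CPM, while FGB (0.67, SE 0.03) and APOE (0.64, SE 0.03) rose. Hepatocyte nuclear factors had 3 of 16 higher and 9 lower, including FOXA3 (-0.83, SE 0.05), PROX1 (-0.56, SE 0.03) and CEBPA (-0.48, SE 0.04). Fetal liver and carcinoma markers had 7 of 15 higher and 4 lower, with IGF2 (0.69, SE 0.05) and GOLM1 (-0.93, SE 0.04). Drug and steroid metabolism had 6 of 18 higher and 6 lower (GSTA2 1.99, SE 0.15; UGT1A1 -0.81, SE 0.12), and bile acid synthesis and transport 3 of 12 higher and 6 lower (HSD3B7 -1.08, SE 0.08). Wnt/beta-catenin targets had 3 of 14 higher and 8 lower, with DKK1 (1.04, SE 0.03), which encodes a secreted Wnt antagonist, and LEF1 (-1.27, SE 0.15).

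Interferon-stimulated genes had 4 of 16 higher and 8 lower; OAS3 fell from 47.7 to 18.9 CPM, and MX1 (-1.36, SE 0.14) and OAS1 (-1.23, SE 0.14) fell, while IFIT1 rose (0.92, SE 0.16). NF-kB and inflammatory genes had 4 of 18 higher and 10 lower, with the apoptosis inhibitor gene BIRC3 falling from 60.1 to 28.3 CPM and LCN2 from 5.96 to 0.751 CPM. Immediate-early genes had 6 of 16 higher and 5 lower (DUSP1 0.72, SE 0.04; KLF4 -1.37, SE 0.10). Mesenchymal transition and matrix genes had 7 of 24 higher and 8 lower: the transcription factor gene ZEB2 (-1.96, SE 0.16) and TAGLN (-1.03, SE 0.06) fell and CCN2 rose. COL4A2 was near the limit of detection, with 1 count in wild type and 44 in the knockout, a ratio of 48.4 (95% interval 8.24 to 1953). Receptor tyrosine kinases and growth factors had 5 of 16 higher and 7 lower, with EGFR (-0.48, SE 0.03), IGFBP3 (-1.30, SE 0.04) and INSR (0.48, SE 0.03).

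Markers of other cell types were measured as well. Of 6 stromal and fibroblast markers 4 were higher and 2 lower, and the abundant one was COL1A2; PDGFRB rose from 7.36 to 14.3 CPM. The 1 endothelial marker tested, PECAM1, fell (-1.46, SE 0.15), as did the 3 immune markers, CD68 (from 16.8 to 8.38 CPM), LYZ (-0.74, SE 0.03) and CD14 (-0.48, SE 0.12). Cholangiocyte markers had 2 of 8 higher and 2 lower, with SPP1 and SOX9 (-0.42, SE 0.04). Of 12 commonly used reference genes 5 were higher and 3 lower, including GAPDH, which fell from 2441 to 1800 CPM (log2 fold change -0.44, SE 0.03).

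Adjusted over the list alone, the counts of members higher and lower were the same in every list but 3: glycolysis had 6 higher, other ubiquitin-conjugating enzymes 11 higher and mitosis 13 lower. The median, the mean and the camera direction differed in sign in 9 lists, none past the threshold: kinase inhibitors, p53-responsive genes, lipid synthesis, proteasome, immediate-early genes, mesenchymal transition, growth factors, the BCL2 family and fibroblast markers.

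Neighbouring genes moved together along the chromosomes, a pattern looked for after the fold changes had been seen. Of 286 regions of 10 Mb, 76 had a median log2 fold change past the threshold of a permutation test against random gene sets, adjusted over the 286 regions, 38 higher and 38 lower in the knockout. The longest run was on chromosome 10 from 60 to 140 Mb, where the median over 349 genes was 0.40 and 86.8% of genes were higher. The 314 tested genes of chromosome 22 had a median of -0.30, the 448 genes in the first 50 Mb of chromosome 1 a median of -0.26, and the 220 genes from 100 to 170 Mb of chromosome 6 a median of 0.25. On chromosome 19 the median was -0.40 in the first 10 Mb, 0.22 from 10 to 20 Mb and -0.25 from 20 to 50 Mb. The 3 knockout libraries shared these shifts closely, with an SD between libraries of 0.00225 for chromosome 10 and 0.0191 for chromosome 22. UBE2S lay in a neighbourhood with a median of -0.03. CHAF1A, UHRF1, CEBPG, UBE2J2, MCL1, BCL2L2, AEN, NDUFB8, RPL4, RPL8 and TBP changed sign once the shift of their neighbours was taken off. FZR1, CDC20, KIF11, CDKN1B, PSMB4, RPLP1 (0.084) and RPS16 (-0.064) kept their sign but lost their call, and others kept it with a smaller change, such as ANAPC16, CDC34 and GAPDH (-0.12). The DNA replication list was no longer called. With the preset correlation the other 8 lists still passed, and HIF-responsive genes (adjusted p = 0.016) and NF-kB genes (adjusted p = 0.026) passed in addition, both lower; an estimated correlation was not tried with the shift removed, and without its removal both had an adjusted p of 0.45.

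**Figure D4:**
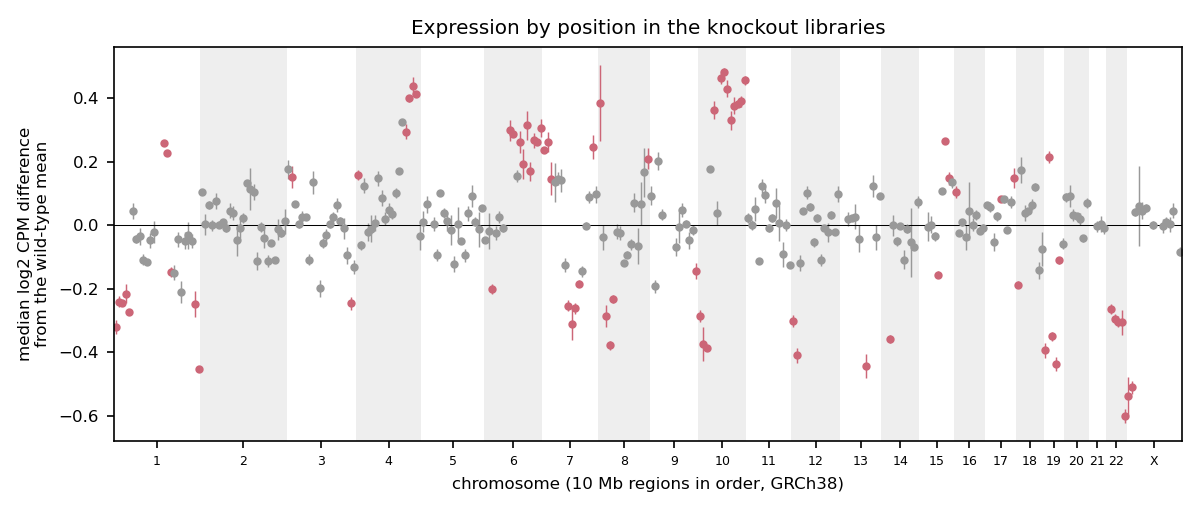
Median log2 CPM difference from the wild-type mean over the genes of each 10 Mb region, in chromosome order (GRCh38); points are the mean and bars the SD of the 3 knockout libraries, and regions past the permutation threshold are in red. Runs of adjacent regions shift together, such as chromosome 10 from 60 to 140 Mb (0.40) and chromosome 22 (-0.30).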

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

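Removing the neighbourhood shift and the trend in GC content and length were chosen after the data had been seen; the other alternatives were planned. UBE2S kept its direction and its call under each alternative run. The number of called genes was 7975 and stayed between 6747 (DESeq2) and 8457 (without wild-type replicate 1) under the other scalings, filters and tools and with each library left out, and the share of calls higher in the knockout stayed between 47.9% and 51.1%. It was 6472 at a threshold of 0.01. It was 814 with an absolute log2 fold change of at least 1 and 1008 when tested against a fold of 1.5, since these ask for larger changes. Libraries with the same number did not deviate together (correlations of 0.02, -0.04 and 0.02) and not every library correlated best with its own number, so the numbers gave no pairing. The replicate block gave 7913 calls and 5 lists, without DNA replication (adjusted p = 0.066), ATF4 targets (0.066), ribosomal proteins (0.066) and coagulation (0.074). The 9 lists became 5 with at least 50 counts in 3 libraries, 14 with DESeq2, 28 with fry for direction and 37 with fry for change either way, which do not compare a list with other genes, and 0 with an estimated correlation. The cause of these differences was not tested. For the YAP/TAZ and metallothionein lists the estimates were -0.023 and -0.074, below the preset 0.01, so a higher correlation is not why these lost their call. Histones and chaperones had estimates of 0.0131 and 0.0126, close to the preset. Their unadjusted camera p still rose from 3.2e-05 to 0.015 and from 5.6e-04 to 0.028 with the estimated correlation. The remaining called lists had estimates from 0.021 (DNA replication) to 0.106 (ribosomal proteins). The p-values with an estimated correlation therefore do not reflect a higher correlation alone. DESeq2 added glycolysis (adjusted p = 0.024), HIF-responsive genes (0.017), hepatocyte nuclear factors (0.024) and NF-kB genes (0.037), all lower. The 14 also hold the immune markers (0.037, lower), which were too few for camera in the main analysis, where 3 members passed filterByExpr against 7 with DESeq2. With the neighbourhood shift removed from the edgeR values, glycolysis (median -0.046, camera adjusted p = 0.83) and hepatocyte nuclear factors (median -0.12, 0.55) did not pass. HIF-responsive genes (0.016) and NF-kB genes (0.026) then did. With a library left out there were 5 to 10 lists. Cholesterol, histone, metallothionein, chaperone and YAP/TAZ lists passed in each of these; those that were lost were among DNA replication, coagulation, ATF4 targets and ribosomal proteins, whose adjusted p was then 0.052 to 0.13, with 5 lists without knockout replicate 1 or 3, 6 without wild-type replicate 3, and 7 without wild-type replicate 2 or knockout replicate 2. With library totals alone the ribosomal list had an adjusted p of 0.051; with the GC and length trend removed it had 0.095 and the coagulation list 0.053. With fry the p53 list, of median 0.11, and the fibroblast list, of median 0.52, were called lower. With the neighbourhood shift removed, 7233 genes were called, 6156 of them also called before and 5928 of these in the same direction. The log2 fold change of UBE2J2 became 0.11, CHAF1A 0.035, UHRF1 0.025, CEBPG 0.081 and BCL2L2 0.046, and that of AEN -0.025, NDUFB8 -0.032, MCL1 -0.075, RPL8 -0.070, TBP -0.055 and RPL4 -0.17; RPL4 alone stayed past the threshold (adjusted p = 1.3e-04). Over all named genes and alternatives, 3085 values kept direction and side of the threshold, 97 lost the call and 11 reversed. UBE2E2, AMACR and LGR5, with few counts or small changes, lost it most often. In simulated data with these library sizes and 3 libraries per group, 58% of changes of 0.3 were found. Only 200 genes were changed there, against 7975 called in the data, so the adjusted threshold was stricter than in the data. The 58% is therefore not the share of such changes found in the data.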

Other observations

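The lists of antigen presentation, Notch, collagen, Wnt ligand and polyadenylated histone genes, the tests of chromosome positions, near-lost genes and histones, and the genes first named here were chosen after the fold changes had been seen. A list of genes of MHC class I antigen presentation, which load peptides for display to T cells, with the regulators IRF1 and NLRC5, guanylate-binding proteins and ligands of natural killer cell receptors such as MICB, had 16 of 23 members lower in the knockout and 2 higher, with a median log2 fold change of -0.40. Since the list was written from genes already seen to change, no p-value is given for it. GBP1 fell from 23.9 ± 1.13 to 3.97 ± 0.484 CPM, GBP2 from 29.8 ± 0.222 to 6.14 ± 0.591 CPM and the peptide transporter gene TAP1 from 7.76 ± 0.730 to 2.43 ± 0.0749 CPM. The immunoproteasome genes PSMB9 (-2.13, SE 0.25) and PSMB8 (-1.21, SE 0.15) fell as well, while PSMB10 was not called (0.048, SE 0.08) and GBP3 (0.81, SE 0.22) and the ligand gene ULBP3 (0.99, SE 0.14) rose. HLA-C fell from 691 counts to 31, although reads of HLA genes can be shared or lost where an allele differs from the reference.

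Other families changed in opposite directions. Among 21 collagen genes 10 were higher and 10 lower. COL1A2 was nearly lost while COL5A2 rose from 704 ± 15.1 to 1299 ± 12.8 CPM, COL18A1 from 300.5 ± 8.47 to 492 ± 8.07 CPM and COL12A1 from 40.8 to 122 CPM, and COL9A2 fell from 51.0 to 13.8 CPM. Of 18 genes of Wnt ligands, Frizzled receptors and coreceptors, 8 were higher and 7 lower: WNT5A was nearly lost, FZD2, FZD5 and FZD8 (1.27, SE 0.10) rose, and FZD1 (-0.66, SE 0.06) and LRP5 (-0.46, SE 0.04) fell. Of 16 Notch genes 6 were higher and 6 lower. Besides NOTCH3, NOTCH2 (0.48, SE 0.03), JAG1 (0.42, SE 0.03) and the target gene NRARP (0.98, SE 0.13) rose, while the target genes HEY1 (-0.98, SE 0.13) and HES1 (-0.40, SE 0.06) fell.

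The 3 against 3 libraries allow 10 splits, too few for a share under 0.05. The real split gave 7975 genes and each of the others 0, with at most 99 genes at an unadjusted p below 0.05. The other splits mix wild-type and knockout libraries within a group, which widens the spread within groups. Few calls were bound to follow there, so they decide nothing. For the gene lists, the real split alone (1 of 10) gave as many as 9, and the highest of the others was 7, where wild-type replicate 1 was grouped with knockout replicates 1 and 2.

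Across genes, which are not independent replicates, the log2 fold change of a gene correlated with the median of its 50 nearest neighbours with a Spearman rho of 0.397, against at most 0.0388 in 100 shuffles of gene positions. A trend in GC content and transcript length does not account for this, as rho was 0.392 after its removal, nor do differences between libraries of 1 group, where rho reached at most 0.159. The real split alone (1 of 10) gave so large a rho, and the highest of the others, which keep part of the contrast between the groups, was 0.342. A candidate explanation, not favoured over others by any value here, is that DNA copy number differed between the knockout and wild-type cells, for example because the knockout cells grew from 1 or few cells of a line with unstable chromosomes: 85 ribosomal, proteasome and respiratory chain genes, scattered over the genome, followed their neighbours with a rho of 0.575 (Pearson 0.740, permutation p = 1e-05, the smallest that 100000 resamples can give), as any cause that acts on whole regions would predict. Copy number was not measured, and regional differences in chromatin, a batch shared by each group and the loss of UBE2S itself stay open.

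In the knockout, 24 genes with at least 5 CPM in wild type had a log2 fold change of -4 or lower, and among genes with at least 5 CPM in the knockout 1, NOTCH3, had one of 4 or higher. Loss of chromosome segments with several genes does not account for these as a set, since the nearest tested gene on either side had a median log2 fold change of -0.075, with 4 of 48 such neighbours below -1. One of these was TMEM200C beside L3MBTL4 on chromosome 18: both had 0 counts in the knockout against 216 and 613 in wild type, at least 65.5-fold and 186-fold lower, so a local deletion may underlie that pair. The others were HSD17B2 beside SDR42E1 (673 wild-type counts against 137), PSAPL1 within SORCS2 (273 against 35) and RPS6KA3 near CNKSR2 (41613 against 18053). Since PSAPL1 lies inside the span of SORCS2, it is not a separate neighbour of that gene. Some nearest tested genes lay far off, up to 2018 kb for ETS1, and say little about a shorter segment. Reads shared with paralogs are unlikely to explain 22 of the 24, whose wild-type estimates were whole numbers, but stay open for DSG3 and HLA-C (8.33% of the set), whose estimates were not. Deletions of single genes, silencing of promoters in the cells from which the knockout was grown, and an effect of UBE2S were not tested and stay open.

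The histone transcripts fell by 0.61 in the median, with an SD between libraries of 0.0347 in wild type and 0.0335 in the knockout. A shift of their chromosome regions does not account for this when genes other than histones are taken as the neighbours. The 20 nearest such genes had a median log2 fold change of 0.045, against the direction of the histones. The histone median was -0.65 after subtraction of these 20 genes, and -0.40 (camera adjusted p = 0.0020) after that of the 50 neighbours. Those 50 included 8 to 24 histones (median 19), so this subtraction took part of the histone change from itself. Fewer cells in S phase stays open, since the DNA replication list does not decide: 15 of its 32 genes were lower and 5 higher, its median was -0.10, which is 0.170 times that of the histones, and with the neighbourhood shift removed it was -0.057 and not called (camera adjusted p = 0.23). Different carry-over of RNA without a poly(A) tail through the oligo(dT) step could give the pattern: polyadenylated histones had a median of 0.23, and 0 other genes annotated as RNA without a tail were tested, so this, fewer cells in S phase and another change in histone mRNA in the cells cannot be told apart.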
